A study of Arabidopsis thaliana with 4 samples.

How the data were processed

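RNA was measured on 4 Affymetrix expression arrays of Arabidopsis thaliana, ecotype Ler-0. The arrays were hybridised with biotinylated RNA from immature inflorescences cut from the primary bolts of 5 week old plants, with 10 inflorescences pooled for each time point. Per the labels' protocols, plants grew at 20 to 22 °C under 16 h of light, inflorescences were cut 11 h into the day, and RNA was extracted with Trizol and cleaned on columns. The group called T0 here was frozen at once (2 arrays). The group called T24 was held for 24 h in the dark at 21 °C, on paper wetted with 50 mL of water in a black box of 2 L (2 arrays). The titles call the 2 arrays of each group biological replicates 1 and 2, and groups and replicate numbers were taken from those titles. The texts do not state whether each replicate had a pool of its own, and p-values measure the spread between these arrays.

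The authors deposited 1 table of log2 expression values for 22746 probe sets on the 4 arrays, summarised with RMA per the submitters' processing notes, which name no version. The log base was taken from RMA's usual output and from the values, which ran from 2.71 to 14.44. Array medians were 6.19 and 6.29 at T0 and 6.09 and 6.08 at T24, so both T0 arrays lay slightly higher. No further normalization was applied for the main results, and other scalings were run as alternatives. The table held no control probe sets. RMA values have no detection calls, and 35.5% of probe sets had a mean under 5 on the log2 scale over the 4 arrays, where real differences are compressed toward 0. With 2 arrays per group, the number of arrays limits the precision.

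Probe sets were named through the platform annotation and updated by gene identifier in the RefSeq gene table of the TAIR10.1 assembly, used for names only. Of the 22746 probe sets, 13513 were paired with 1 gene, 503 with several genes and 8730 with none. Those with several genes were named for none, and those with none are unnamed here. Of the 13513, 13436 matched the gene table, and the other 77 kept the platform's name. For gene lists, each of the 13355 genes was represented by its probe set with the highest mean over the 4 arrays, and 147 genes had more than 1 probe set. Only 1535 of these genes carried a symbol other than their locus code.

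The comparison T24 minus T0 was fitted to all 22746 probe sets without a filter or covariate, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. P-values were adjusted by the method of Benjamini and Hochberg, with calls at an adjusted p under 0.05. Every adjusted p for a gene in the text comes from this limma fit, and every SE is its moderated standard error. Named genes followed a rule written before the data were examined. It took the 10 largest rises and 10 largest falls among single-gene probe sets that passed the threshold, did not overlap between groups and carried a symbol. From each list it took up to 3 passing members with the largest changes, and 1 passing member of the opposite direction. A list with no passing member gave its brightest one. The rule also named ASN1, SAG12, NYE1, AP3, NAP and ORE1, which are not analysed here because no probe set was paired with their locus codes. Every gene named by the rule had a single probe set.

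The 27 gene lists and 11 symbol families were also written before the data were examined, and 89 of the 485 listed genes were measured by name. The lists for ammonium assimilation and asparagine synthesis, for jasmonate and for low oxygen had 0 measured members, as had the ERF/AP2, cellulose synthase and SAUR families. The 20 lists and families with at least 3 measured members were tested with camera, which compares a list's genes with all other genes, at a preset correlation of 0.01 and with adjustment over the 20. Camera with an estimated correlation and fry, a test of whether a list's genes move one way on balance, were run as alternatives. With an estimated correlation, camera tests on the 2 residual degrees of freedom, which leaves it little power here. Another 6 lists and 45 families sharing the letters of their symbols were made after the data had been seen, and adjusted among themselves. The result of 1 of the 20, a symbol family, is not reported here, nor are its members.

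Both tests were tested on simulated data with the means and spread of this comparison. With 5000 of 22746 simulated probe sets changed, 31.8% of changes of 1 on the log2 scale, 81.7% of changes of 2 and 91.3% of changes of 3 were recovered, and 4.41% of calls were false. With 200 of 22746 changed, 0 were recovered at any of those sizes, and with none changed there were 0 calls. In the simulated list test, 0 of 20 lists passed without a change, and 1 passed when 1 list of 15 genes was raised by 1. The simulated probe sets varied independently and shared no difference between replicate numbers. These rates therefore do not tell how either test behaves where genes vary together.

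The alternatives were the replicate number as a block, eBayes with an intensity trend or robust, quantile normalization of the deposited values, centring on array medians or on 3 reference genes, a filter at a mean of 5, 1 probe set per gene, stricter thresholds, every single-gene probe set in the lists, and leaving out each array in turn. A count without organelle-encoded probe sets was added after the data had been seen, as were the reference-gene centring of the count and the median and quantile scaling of the lists.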

Results

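Expression was measured in detached immature inflorescences of Arabidopsis, a tissue rich in young flower buds, before and after 24 h in the dark with water but without a carbon supply from the plant. There were 2 arrays of inflorescences frozen at harvest (T0) and 2 of inflorescences held for 24 h (T24), with 10 inflorescences pooled for each time point. Values are log2 signals, and changes are T24 minus T0 with the standard error of the fit. Across probe sets, the correlation between arrays was 0.954 within T0, 0.961 within T24 and between 0.839 and 0.873 across the groups.

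The comparison of T24 with T0 asks how the transcriptome differs after a day of dark holding. Cutting, darkness, the loss of supply from the plant, the wet closed box and 24 h of time all go together in it. There was no attached, light-held or sugar-fed group, so their effects cannot be told apart. As lists, genes of amino acid breakdown and of autophagy were higher after 24 h, and genes of the Calvin cycle and of cytosolic ribosomal proteins were lower. These 4 calls were made by camera and did not hold with an estimated correlation (adjusted p = 0.57 for each). The estimated correlations were -0.096, 0.158, 0.689 and 0.977, and the unadjusted p-values in camera 0.0325, 0.134, 0.175 and 0.285, in the order given. With 2 residual degrees of freedom a list could hardly pass that alternative, so it does not decide whether correlation between genes undoes the calls. In fry, the other alternative, amino acid breakdown (adjusted p = 0.00274) and the Calvin cycle (0.0441) passed. Autophagy (0.0808) and ribosomal proteins (0.084) did not pass in fry, so their calls rest on camera at its preset correlation. Among genes with a symbol, the largest rise was that of PAP85, a vicilin-like seed storage protein, from 3.80 ± 0.74 to 11.99 ± 0.53 (SD, n = 2 each), a change of 8.19 ± 0.48 (SE) or 292-fold. HIS1-3, a linker histone known to respond to drought, rose by 6.61 ± 0.17 (97.5-fold), from 4.33 ± 0.04 to 10.93 ± 0.05 (SD, n = 2 each). BGLU45, a beta-glucosidase of monolignol glucosides, rose by 5.45 ± 0.27, and the carboxypeptidase-like gene scpl38 by 5.13 ± 0.55. Genes for a pair of enzymes of leucine breakdown also rose, MCCA by 4.98 ± 0.22 and IVD by 4.78 ± 0.38. AKINBETA1, a regulatory subunit of the energy-sensing kinase SnRK1, rose by 4.97 ± 0.26 (31.3-fold). The salt-induced gene SIS rose by 4.78 ± 0.46, the growth regulator ARL by 4.61 ± 0.20 and the defensin-like gene PDF1.4 by 4.53 ± 0.29. Limma's adjusted p for these 10 genes lay between 0.0143 and 0.0195.

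The largest fall among genes with a symbol was that of SHT, an acyltransferase that makes spermidine conjugates in the anther tapetum, which fell by 6.19 ± 0.39 (73.3-fold lower), from 10.41 ± 0.66 to 4.21 ± 0.26 (SD, n = 2 each). ATA27, an anther beta-glucosidase, fell by 4.50 ± 0.82. The glutathione transferase GSTU20 fell by 5.18 ± 0.29 (36.2-fold lower). The cold-regulated chloroplast proteins COR15A and COR15B fell by 4.97 ± 0.82 and 4.41 ± 0.60, and for COR15A the 2 arrays at T0 were far apart (10.15 ± 1.62, SD, n = 2). The thaumatin-like gene ATLP-1 fell by 4.94 ± 0.26. Among genes of the cell wall and its polymers, TBL26 fell by 4.75 ± 0.29 and CSLA01, of a family of mannan synthases, by 4.55 ± 0.52. The SKU5-like gene sks18 fell by 4.48 ± 0.57. 3xHMG-box2, a protein of condensed mitotic chromosomes, fell by 4.16 ± 0.33. Adjusted p for the 10 falls lay between 0.0143 and 0.0443. Where a group's mean lay under 5, as for PAP85 at T0 and SHT at T24, the signal is near the background, and the size and rank of a change are approximate.

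**Figure D1:**
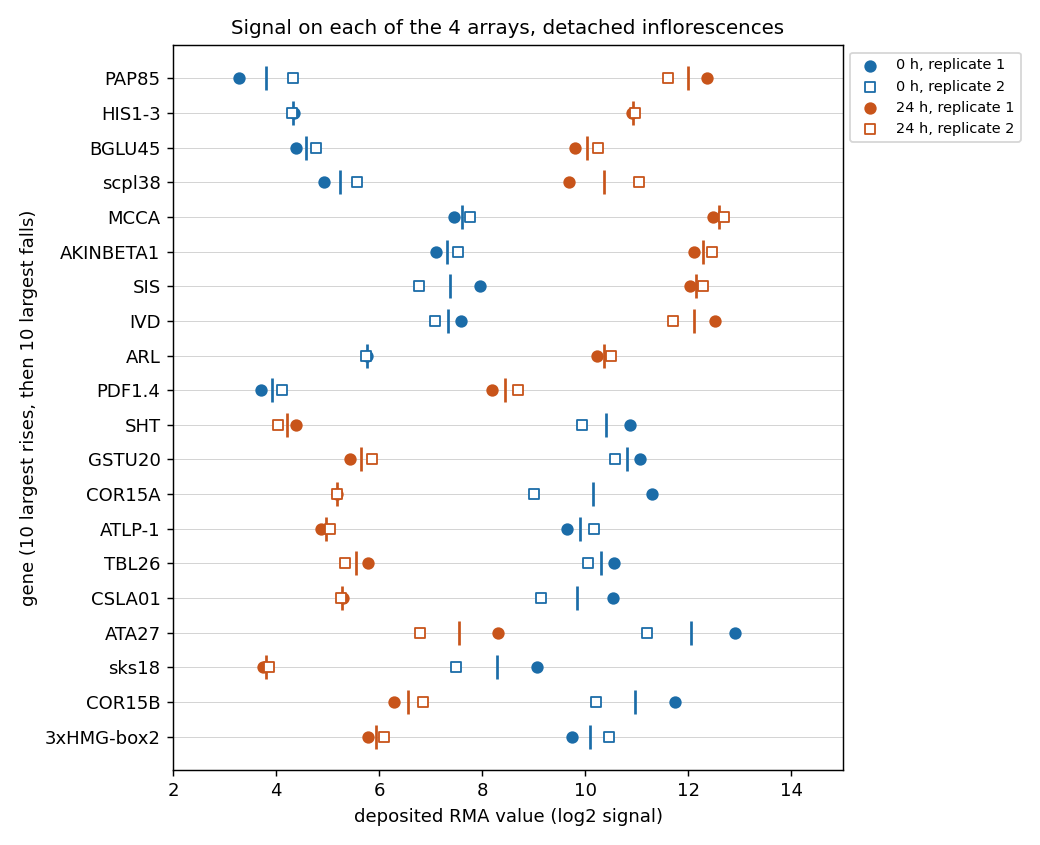
Deposited log2 signal (horizontal axis) of the 10 largest rises and the 10 largest falls among genes with a symbol (vertical axis). Blue marks stand for T0, orange for T24, filled circles for replicate 1, open squares for replicate 2 and vertical bars for group means. The groups do not overlap for any of the 20 genes, which the naming rule required. PAP85 goes from a mean of 3.80 to 11.99 and SHT from 10.41 to 4.21.

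In all, 3010 of 22746 probe sets passed an adjusted p of 0.05, 1454 higher and 1556 lower at T24, and 2939 of them differed by 2-fold or more. Of those that passed, 799 were 4-fold or more higher and 648 were 4-fold or more lower. On these arrays 1608 of the 13355 genes measured by name passed, 808 higher and 800 lower. The groups did not overlap for 57.4% of probe sets, where chance gives 33.3% for 2 against 2. The smallest adjusted p was 0.0143, and leaving out T0 replicate 1, T0 replicate 2, T24 replicate 1 or T24 replicate 2 left 0 probe sets past the threshold in limma, with 5942, 5844, 5038 and 4888 at an unadjusted p under 0.05.

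The list for the breakdown of branched-chain amino acids, lysine and proline had 11 of 19 genes measured. Of these 8 rose, 1 fell and 2 did not pass, and adjusted over the list alone 9 rose and 1 fell. PRODH1 and P5CDH, its genes for proline-degrading enzymes, were not measured. The list's median change was 2.44, with an adjusted p of 5.05e-06 in camera, 0.00274 in fry, and 0.57 with an estimated correlation. Besides MCCA and IVD, the lysine-degrading enzyme LKR/SDH (AT4G33150) rose by 3.67 ± 0.46, from 9.09 ± 0.74 to 12.76 ± 0.44 (SD, n = 2 each). The other 5 that rose were MCCB, ETFQO, OAT, ALDH6B2 and HML1, by 1.22 to 3.24. The member that fell was AT5G09300, by 3.00 ± 0.31. It was the only measured subunit gene of the branched-chain ketoacid dehydrogenase in the list.

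Autophagy genes were higher as a list in camera, with 2 of 15 measured members past the threshold. ATG8E rose by 4.16 ± 0.50 (17.9-fold) and ATG8F by 1.99 ± 0.33. Both encode ATG8 proteins, which are attached to the forming autophagosome membrane. Much of the list is this 1 family: ATG8A to ATG8I were all measured, with changes of 0.77 to 4.16. The measured members outside it had no call, and ran from -0.07 (ATG1A) to 0.94 (ATG1B). The other 13 did not pass, among them ATG8H at 3.35 ± 1.24 and ATG8I at 1.56 ± 0.31; adjusted over the list alone, 4 rose. The median change was 0.94, with an adjusted p of 0.000408 in camera, 0.0808 in fry and 0.57 with an estimated correlation. Of 6 measured senescence genes 2 rose, over all genes and adjusted over the list alone. They were the transcription factors WRKY22, by 2.56 ± 0.48, and EIN3, of the ethylene pathway, by 2.83-fold (9.32 ± 0.38 to 10.82 ± 0.02, SD, n = 2 each). This list's median was 1.11 (adjusted p = 0.0463 in camera, 0.0967 in fry and 0.57 with an estimated correlation). Without T0 replicate 1 its adjusted p in camera was 0.0519, and without T24 replicate 1 it was 0.102. Of 5 proteases and nucleases, the vacuolar processing enzyme GAMMA-VPE rose by 1.75 ± 0.22, and 4 did not pass (1 also adjusted over the list alone; adjusted p of the list 0.455 in camera).

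Calvin cycle genes fell in 3 of 4 measured cases, also adjusted over the list alone. SBPASE fell by 2.68 ± 0.22 (6.39-fold lower), from 11.20 ± 0.16 to 8.53 ± 0.21 (SD, n = 2 each). The phosphoglycerate kinase PGK2 (AT1G56190) fell by 2.36 ± 0.21 and the Rubisco activase RCA by 1.56 ± 0.18, while PRK, at -0.92 ± 0.40, did not pass. The list had a median of -1.96 and an adjusted p of 0.00248 in camera, 0.0441 in fry and 0.57 with an estimated correlation. Among 7 photosystem and antenna genes, the minor antenna genes went opposite ways: LHCB4.3 fell by 3.56 ± 0.29 and LHCB4.2 rose by 1.61 ± 0.28. The other 5 did not pass, adjusted over the list alone it was again 1 and 1, and the list's adjusted p was 0.958 in camera. The 69 measured plastid-encoded genes gave 0 calls in limma, with 5 at an unadjusted p under 0.05. Their signals were higher on the replicate 2 arrays, with a median difference (replicate 1 minus replicate 2) of -1.54. With the replicate number as a block, 5 of the 69 rose and 3 fell, and the list, made after the data had been seen, was higher at T24 (adjusted p = 0.0201 in camera). Without the block the adjusted p was 0.177 in camera and 0.778 with an estimated correlation. The 16 measured mitochondrion-encoded genes gave 0 calls in limma, with 4 at an unadjusted p under 0.05. Under the block 4 of them rose and 0 fell, and this list, also made afterwards, was higher too (adjusted p = 0.0247 in camera, against 0.0802 without the block and 0.597 with an estimated correlation).

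For chlorophyll synthesis, 1 of 5 measured genes passed: GSA1, of the early tetrapyrrole pathway, fell by 1.63 ± 0.23. Adjusted over the list alone 4 fell, and the list's adjusted p was 0.0711 in camera. In starch metabolism 1 of 3 genes fell (2 adjusted over the list alone; list adjusted p 0.261 in camera), APL3 of starch synthesis by 2.03 ± 0.37. In flavonoid synthesis 1 of 3 fell, also adjusted over the list alone (list adjusted p 0.0758 in camera), the glycosyltransferase gene UGT78D2, which was 4.28-fold lower (8.00 ± 0.49 against 5.90 ± 0.29, SD, n = 2 each). The single chlorophyll degradation gene, NOL, changed by 0.33 ± 0.30 and did not pass. The list for fatty acid oxidation and the glyoxylate cycle had 2 of 20 genes measured, and neither passed. AIM1, of fatty acid oxidation, stood at 0.27 ± 0.26. ICL, of the glyoxylate cycle, was near the background (4.86 ± 0.35 at T0 and 4.45 ± 0.23 at T24, SD, n = 2 each).

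**Figure D2:**
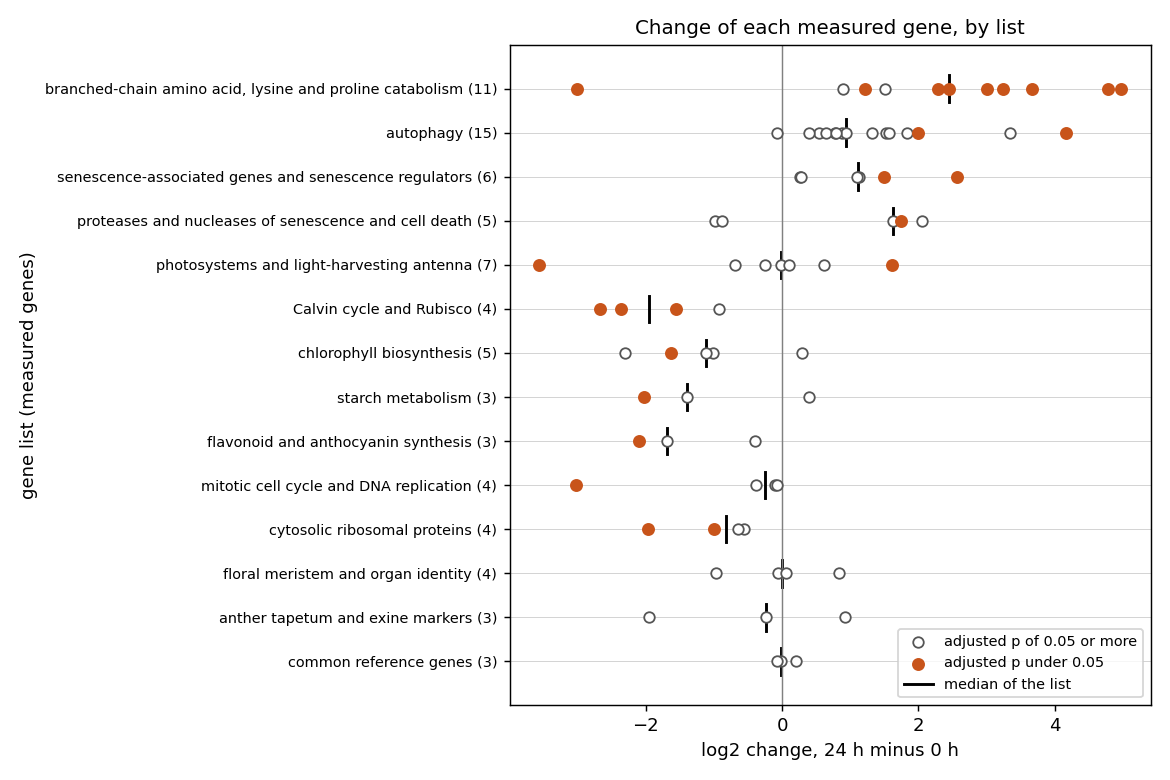
Log2 change from T0 to T24 (horizontal axis) of each measured gene in the 14 lists with at least 3 measured genes (vertical axis, number of genes in brackets), as filled points for genes past an adjusted p of 0.05, open points for the others and black bars for list medians. The catabolism list has a median of 2.44 with 1 gene at -3.00, and the Calvin cycle list a median of -1.96.

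Few of the listed growth genes could be measured by name: 4 of 35 for the cell cycle and 4 of 28 for cytosolic ribosomal proteins. Of 4 cell cycle genes, PRL, which encodes the replication helicase subunit MCM7, fell by 3.03 ± 0.53, also adjusted over the list alone, and the 3 Aurora kinase genes did not pass (list adjusted p 0.326 in camera). Of 4 cytosolic ribosomal protein genes, RPL4D (AT5G02870) fell by 1.96 ± 0.30 and RPL10aB (PGY1) fell from 11.74 ± 0.12 to 10.74 ± 0.07 (SD, n = 2 each); adjusted over the list alone 3 fell. Their median was -0.83 (adjusted p = 0.0237 in camera, 0.084 in fry and 0.57 with an estimated correlation), and without T24 replicate 1 the adjusted p in camera was 0.0546. Of 10 expansin A genes, EXPA15 fell by 3.49 ± 0.36, and of 10 xyloglucan transferase (XTH) genes, EXGT-A3 rose by 2.81 ± 0.38 while XTH32 was 2.82-fold lower (8.70 ± 0.13 against 7.20 ± 0.04, SD, n = 2 each). Neither wall family passed as a list (adjusted p 0.455 in camera for both), and the counts adjusted over the list alone were the same. Most genes of both families had a mean under 5, where changes are compressed, so these list results say little about the genes with signal. With the filter at a mean of 5 the XTH median went from 0.17 to -1.13.

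Markers of flower parts showed few calls. The 4 floral identity genes, the 2 ovule and carpel genes and the 3 tapetum genes gave 0 calls in limma, also adjusted over the list alone, and 1 gene, the tapetum list's SWEET8 at 0.93 ± 0.30, had an unadjusted p under 0.05. The carpel gene SPT, which is in 2 of these lists, stood at 0.84 ± 0.50. The tapetum gene A9 (AT5G07230) stood at -1.95 ± 1.23, with arrays far apart at T24 (9.05 ± 2.01, SD, n = 2). The tapetum list had a median of -0.24 and a mean of -0.42 while camera placed it upward (adjusted p 0.977). The floral list had a median of 0.00014, a mean of -0.03 and a downward camera direction (adjusted p 0.977). That median lies between UFO (-0.06 ± 0.19) and CLV3 (0.06 ± 0.18), whose means were under 5 in both groups. The floral genes with means above 5, SPT and SPL/NZZ (-0.97 ± 0.45), went opposite ways, so the median says little about this list. The single measured pollen marker AT59, a pectate lyase, rose 18.4-fold, from 6.39 ± 0.29 to 10.60 ± 0.05 (SD, n = 2 each).

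Hormone and stress lists had at most 2 measured genes each and were not tested as lists. EIN3 was the only measured member of the ethylene list. In the abscisic acid list COR15A fell, and the dehydrin gene COR47, at 1.92 ± 0.73, did not pass. The cytokinin response regulators RR16 and ARR15 did not pass at -0.49 ± 0.75 and -1.13 ± 0.30, and ARR15 fell adjusted over the list alone. The clock gene GI was at 9.55 ± 0.15 and 9.51 ± 0.02 (SD, n = 2 each), and the defensin gene PDF1.2 at 3.99 ± 0.14 and 4.04 ± 0.34. AKINBETA1 was the only measured member of the sugar starvation list. In the families, 1 of 7 WRKY genes rose (WRKY22), the single NAC gene NAC014 rose by 1.90 ± 0.34, and 1 of 7 Aux/IAA genes rose (IAA18, 1.04 ± 0.20). Among 11 tau glutathione transferases GSTU20 fell and GSTU16 rose by 1.31 ± 0.22, and 1 of 2 heat shock genes fell (Hsp70-2, by 1.69 ± 0.32). Adjusted over the list alone, 2 tau transferases fell and 1 rose, and the other counts were the same. In camera the adjusted p was 0.223 for WRKY, 0.261 for Aux/IAA and 0.455 for the transferases, and fry gave 0.0434 for the transferases. The 3 common reference genes gave 0 calls in limma and 0 at an unadjusted p under 0.05, with GAPC2 at 0.21 ± 0.30; their median was -0.02, their mean 0.04 and the camera direction upward (adjusted p 0.977).

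The calls of APL3, RPL4D, RPL10aB, IAA18, GSTU16 and Hsp70-2 were each lost under at least 1 other scaling, filter or variance model. That of WRKY22 was lost with the replicate number as a block (adjusted p 0.0504 in limma). Of the 3010 calls, 1347 were on probe sets unnamed here, so the lists describe part of the response only.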

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

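Every alternative here was fixed before the data were examined, except those named as added. The count of 3010 probe sets stayed within 1.5 times under the trended fit (2764), the robust fit (2779), quantile scaling (3151), median centring (3105, with 58.2% higher against 48.3%), the filter at a mean of 5 (3240) and the 2-fold limit (2939), and under 2 added ones, reference-gene centring (3273) and leaving out organelle-encoded probe sets (3066). Median centring moved all changes by 0.16 on the log2 scale. With 1 probe set per gene, 1634 of 13355 passed, fewer probe sets being tested. At an adjusted p of 0.01, 0 passed, against 307 with the filter and 871 with reference-gene centring. With the replicate number as a block (replicate block), 6528 passed, among them 3009 of the 3010. Replicate differences at T0 and at T24 correlated at 0.63 across probe sets, but the labels do not say that a number marks a shared batch, and there are only 2 pairs.

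Leaving out 1 array gave 0 calls each time, with 0 of the passing members of every list and family, because a lone array is then assumed to vary like the other group and few degrees of freedom remain; the smallest adjusted p ran from 0.054 to 0.0936. The 57 genes taken by the naming rule kept their direction, where they passed, in all 10 alternatives, but only the 3 scalings could have turned it. The groups of a called gene do not overlap, so leaving out 1 array cannot turn its direction, and the other alternatives leave the change as it was. Under the block A9 gained a call (adjusted p 0.027) and WRKY22 lost its own (adjusted p 0.0504). Of the 49 that passed, 3, 4, 3, 2 and 2 lost their calls under the trend, quantile scaling, median centring, reference-gene centring and the filter.

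Of the 20 lists and families, 5 passed in camera. This became 0 with an estimated correlation, 3 in fry (1 of them gained, the tau glutathione transferases), 3 of the 17 still tested with the filter, and 3 to 7 when 1 array was left out (lowest without T24 replicate 1). The senescence list lost its call under median centring, and chlorophyll synthesis gained one under reference-gene centring and under quantile scaling. With the replicate block 7 passed, chlorophyll synthesis and flavonoid synthesis being added. Counts of passing members under the block were 8 for autophagy, 4 for chlorophyll synthesis, 2 each for proteases, starch and flavonoids, and 1 each for ovule, tapetum and cytokinin. The filter and reference-gene centring each gave 4 for autophagy, 2 for chlorophyll synthesis, 1 for ribosomal proteins and 0 for Aux/IAA. In the added scalings, quantile gave 2 for chlorophyll synthesis and 0 for starch, ribosomal proteins and Aux/IAA, and median centring gave 1 for ribosomal proteins and 0 for starch and heat shock genes. The cause of these differences was not tested. Medians of 5 lists changed sign under median centring (fatty acid oxidation with the glyoxylate cycle, photosystems, clock, reference genes and expansin A). Leaving out T0 replicate 1, T0 replicate 2, T24 replicate 1 or T24 replicate 2 turned 5, 5, 2 and 6 medians, the filter 3 (XTH from 0.17 to -1.13), reference-gene centring 2 and quantile scaling 1. None of the lists turned in any setting was among the 5 that passed in camera. Signals near the background limit depth: 8068 probe sets had a mean under 5.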

Other observations

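The genes and lists in this part, and all tests but that on mitochondrial transcripts, were chosen after the data had been seen. AT59 was the only measured gene of the pollen list fixed beforehand. In a list of 24 pollen and sperm cell genes made afterwards, 9 rose, 0 fell and 15 did not pass in limma. Among the 9 were the pollen tubulin TUA1 (2.61 ± 0.34), the sperm histone MGH3 (2.61 ± 0.42), CHX15 (2.15 ± 0.34) and ANX1 (2.26 ± 0.26), a receptor kinase gene of the pollen tube. Those that did not pass included ACT11 (-0.03 ± 0.54) and TET11 (-0.13 ± 0.25). Other genes known from pollen were picked because they rose. They were PLIM2a and PLIM2b, for actin-bundling proteins, by 3.76 ± 0.26 and 2.95 ± 0.31, the receptor kinase gene ANX2 by 3.85 ± 0.61, and the peptide genes RALFL25 and RALFL26 by 3.65 ± 0.24 and 3.71 ± 0.18. In the RALFL family of 10 genes these 2 rose and 1 fell (RALFL34, by 3.12 ± 0.20), with a median of 0.15 and an adjusted p of 0.844 in camera. In a list of 7 histone genes, HIS1-3 rose, HTB1 and HTB2 fell, with changes of -2.42 ± 0.27 and -3.02 ± 0.21, and 4 did not pass. Adjusted over the list alone, 2 rose and 5 fell. The list had a median of -1.19 and a mean of -0.14, and was placed downward by camera (adjusted p 0.133) and upward by fry (adjusted p 0.113). Of 6 meiosis genes 1 fell, ATMND1 by 1.25 ± 0.24 (camera adjusted p 0.133).

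Outside these lists PPDK, which can feed amino acid carbon into sugar synthesis, rose by 4.38 ± 0.33. The lipase gene SDP1 of oil breakdown rose by 2.53 ± 0.21. In the list of fatty acid oxidation and the glyoxylate cycle fixed beforehand, AIM1 and ICL (-0.41 ± 0.27, near the background) did not pass. Of 6 genes for auxin conjugation 3 rose, WES1 by 4.39 ± 0.32, IAGLU by 3.60 ± 0.43 and GH3.17 by 2.28 ± 0.36. The list's adjusted p was 0.133 in camera, and adjusted over the list alone GH3.9 fell, with a change of -0.99 ± 0.29. Of 20 beta-glucosidase genes 3 rose and 4 fell. Among genes known here only by locus code, AT1G12010, an ACC oxidase gene of ethylene synthesis, rose by 7.69 ± 0.78, and AT2G05540 rose 128-fold, from 5.95 ± 0.04 to 12.95 ± 0.04 (SD, n = 2 each). AT4G30650 fell by 6.41 ± 0.61. Of 45 symbol families tested in camera, ATG (8 genes, up, adjusted p 0.011) and CRR (5 genes, down, adjusted p 0.0197) passed, and with an estimated correlation the adjusted p was 0.839 for both. All 8 ATG genes are in the autophagy list, so this repeats that list's result.

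The rise of pollen genes may reflect buds that went on to a later anther stage, or a larger share of pollen RNA as other RNA was lost. The list of 24 had a median change of 0.77, which both explanations allow. Its adjusted p was 0.000225 in camera and 0.545 with an estimated correlation, but the list was made after the data had been seen and holds genes already noted as rising, so this test does not support the pattern. Some other anther genes went the other way. SHT and ATA27, named because they were among the largest falls, changed by -6.19 ± 0.39 and -4.50 ± 0.82. The tapetum list fixed beforehand did not move one way (adjusted p 0.977 in camera). In it A9, at -1.95 ± 1.23, passed only under the replicate block, and AMS (-0.24 ± 0.29) and SWEET8 (0.93 ± 0.30) did not pass. Whether the falls of SHT and ATA27 and the pollen rises belong together was not tested. If all pollen RNA had risen by 1 factor, the changes of the 19 members with a mean of at least 5 would spread by about their error. Their SD was 0.91, or 2.32 times the mean standard error, which lies between the limits set for and against that explanation. The 2 explanations cannot be told apart here, since bud stages were not separated on these arrays.

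Plastid-encoded transcripts differed between replicate numbers as a group. In limma 0 of 69 genes passed between replicate numbers and 53 had an unadjusted p under 0.05. Nuclear genes differed as well: 0 of 13270 passed, and 2837 had an unadjusted p under 0.05. Of these 13270 genes, 5442 were higher on replicate 2 at both times and 3861 on replicate 1. The 69 genes had a median difference (replicate 1 minus replicate 2) of -1.01 at T0 and -1.72 at T24, and 53 were higher on replicate 2 at both times; ycf3 read 4.18 and 9.41 at T0 and 4.73 and 10.13 at T24. Array-wide scaling is argued against, since the lowest median among 10000 nuclear lists matched on mean signal was -0.24. More green tissue in the replicate 2 pools is argued against by nuclear photosynthesis genes, whose median was 0.46, with 11 of 16 higher on replicate 1 at both times. A lower selectivity for RNA with poly(A) tails stays open. Mitochondrion-encoded genes, 16 taken by their platform names, had a median of -0.46, which lies between the limits set beforehand for and against this explanation. Of these, 13 were higher on replicate 2 at both times. Their single differences ran from -3.63 (ccb382) to 0.53 (nad2). Some of them, nad2 and matR included, had a mean under 5, where differences are compressed. Beyond the share of green tissue no biological explanation was tested, because the labels name no difference between the replicates.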
